A study of Mus musculus with 7 samples.

How the data were processed

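RNA of the left plantaris was pooled from 6 mice at each of 7 time points and hybridised to 1 Affymetrix Mouse Gene 1.0 ST array per pool, per the series' design text and the labels. RNA was extracted with Trizol and labelled with biotin, per the labels' protocols. The labelling protocol gives 250 ng of RNA as the input and the design text 100 ng, and which was used is not settled here. The deposited values are intensities on a linear scale, 1 per transcript cluster and array, normalized between arrays by the authors. Partek is named in the submitters' processing notes without a version or a step. The background correction, the summarization, the normalization method and the genome build are not given in the sources used here. The lowest intensity of an array was 5.2 to 5.8, and values were taken to log2 with a pseudocount of 0.

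Of 35556 rows, 23410 were in the platform annotation. A single gene symbol was given for 21789 of them and several symbols for 1621. The other 12146 rows are unnamed here, and no gene was named from a row with several symbols. Entrez IDs matched 21698 single-symbol rows to RefSeq genes of GRCm38.p6, used only for names and gene types, and 0 symbols changed. The single-symbol rows held 19938 genes. Where a gene had more than 1 row (999 genes), the row with the highest mean log2 value stood for it. A gene was kept when its value reached the median of all rows on at least 1 array, which left 12102 genes.

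Each later day was set against d0, the control named in the labels, as a log2 ratio of 1 array to 1 array with no test, and genes past 2-fold were counted. The 8 highest and 6 lowest genes of each day were named, leaving out predicted genes, clones, receptors, small RNAs and antigen receptor segments. Up to 4 members with the largest ratios were named of each list, on the day its median lay farthest from 0, with their values on other days. Also named were the 8 genes with the largest slope each way and a fixed set that held the myosins, Fbxo32, Trim63, Col1a1, Col3a1, Cd68 and clock genes. Gene lists for muscle, growth, matrix, cell types, metabolism and stress were fixed, with the tests and the naming rule, before the data were examined. A list's median log2 ratio was placed as a percentile among 10000 random lists of the same size matched on mean expression in 10 bins, if it had at least 4 measured genes. This describes the arrays and is not a test of the condition. Values at percentile 100 or 0 are rounded.

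Trends over time were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) on log2(day + 1), two-sided, with Benjamini-Hochberg adjustment at 0.05. Pools of different animals at each day make up the error of this fit, together with any departure from a straight line. Trends of list medians used Spearman's rho and Pearson's r with all 5040 orders of the 7 arrays, or all 720 orders of 6. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest. The trend fit was tested on simulated data with the 12102 genes and recovered 64.0%, 94.0%, 100% and 100% of 50 genes each that changed in total by 0.5, 1, 2 and 3 on the log2 scale, with 9 false calls. The noise simulated for the trend was independent between genes and arrays, and the changes followed log2(day + 1) exactly. No difference of a whole array was simulated, so these shares may not hold for the real arrays or for other courses. The list ranking found 3 of 3 shifted lists in simulated data.

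The alternatives tried were no filter and a filter at percentile 75, quantile normalization, equal array medians, the mean of a gene's rows, thresholds of 1.5-fold and 3-fold, other scales of the day, each time point left out, random lists without matching, the mean of a list in place of its median, and the mean of the 6 other arrays as the reference. The d14 array as the reference, list trends on values centred per gene, with and without d0, and other filters for neutrophil markers and mitosis genes were added after the data were seen. Markers of bone, marrow and cartilage cells were chosen after the highest genes of d10 were seen, and the genes already seen were left out of those tests. Scanner files were not used here, so detection above background could not be given per gene.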

Results

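Gene expression was measured in the left plantaris, a calf muscle made up mostly of fast fibres, of male C57BL/6J mice aged 5 months during regrowth after hind limb suspension. Suspension takes the weight off the hind limbs for 2 weeks and the muscles lose mass; loading then resumes when the animals walk again. Muscle was taken at the end of suspension (d0, the control) and 1, 3, 5, 7, 10 and 14 days later. Each of the 7 time points is 1 array, hybridised with RNA pooled from 6 animals, so there are no replicates. A difference between 2 time points therefore carries no error and no p-value, and the number of arrays limits the precision. The median intensity over the 35556 rows of an array lay between 128.1 and 131.8, and 12102 genes passed the filter on low values. Ratios are given on the log2 scale against d0 unless stated otherwise.

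The comparison of d1 with d0 asks what the return of load did within a day. Genes of sarcomeric stretch sensing and of the heat shock response led. Ankrd1, a titin-associated ankyrin repeat protein, was 12.2-fold higher (log2 3.61), and Csrp3, the muscle LIM protein of the Z-disc, was 8.64-fold higher (3.11). Atf3, a stress-induced transcription factor, was 8.55-fold higher (3.10), Xirp1, an actin-binding protein of repairing myofibrils, 7.48-fold higher (2.90) and Hspa1a, an inducible heat shock protein, 4.94-fold higher (2.30). Ankrd2 was higher by 2.76, the actin crosslinker Flnc by 2.12 and the deubiquitinase Otud1 by 2.08. In all, 79 genes were at least 2-fold higher and 45 at least 2-fold lower at d1 than at d0.

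Of the 19 measured stretch and load responsive genes, 11 were at least 2-fold higher at d1 and none 2-fold lower, with a median of 1.78. Among the 18 heat shock genes the median was 0.92 and all 18 were higher, with Hsph1 at 1.76, Hsp90aa1 at 1.55 and Hspb7 at 1.35. Genes listed as denervation responsive had a median of 0.62, led by the transcription factor Runx1 (1.65) and the growth arrest gene Gadd45a (1.53), with the acetylcholine receptor subunit Chrna1 at 0.75 and the adhesion molecule Ncam1 at 0.74. Unfolded protein response genes had a median of 0.47, with the chaperone Hsp90b1 at 0.98 and the disulfide isomerases Pdia3 and Pdia6 at 0.86 and 0.82. All 38 ribosome biogenesis genes were higher at d1 (median 0.37), among them Gnl3 and Rrp12 at 0.90 and Tsr1 at 0.86. Translation factors had a median of 0.26, and proteasome subunits one of 0.22, in which Psmd11 stood at 0.94. These 7 medians lay between percentile 99.8 and percentile 100 of random lists matched on expression. Set against d14 in place of d0, a reference chosen after the data were seen, the same 7 medians were 1.30, 0.65, 0.68, 0.31, 0.30, 0.19 and 0.17.

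Macrophage markers were higher as well at d1, with a median of 0.34 over 23 genes. The lysosomal glycoprotein Cd68 led them at 2.04, with Lgals3 at 0.65, C1qc at 0.63 and Ctss at 0.59. Oxidative phosphorylation genes were slightly lower at d1, 45 of 51 of them, with a median of -0.08 at percentile 0.28, and fatty acid use genes had a median of -0.05 at percentile 1.22. Slow fibre contractile genes had a median of 0.43 at d1, with 12 of 12 higher, and fibrillar collagen and matrix genes one of 0.28, with 32 of 40 higher, both at percentile 100 (against d14, 0.24 and 0.01). Among the genes with the lowest ratios were Srsy, a Y-linked gene of the testis (-1.59), Arrdc2 (-1.20), the glutathione-degrading enzyme Chac1 (-1.29), the kelch protein Klhl33 (-1.27), Odf3l2 (-1.18) and Sh3rf2 (-1.09). Of the 45 genes 2-fold lower at d1, however, 38 were predicted genes, clones, olfactory or vomeronasal receptors or small RNAs. The d0 array correlated less with the rest over 1194 receptor genes (mean r across genes 0.898) than any other array did (0.962 to 0.972), and 95 of these genes passed the filter. By Pearson's r over the 12102 kept genes it was hardly apart, with a mean r of 0.986 against 0.987 for d1 and 0.989 to 0.992 for the rest. By Spearman's rho over all 35556 rows it did stand apart, with a mean of 0.972 against 0.984 to 0.989 for the other arrays. Of the kept genes, 61.1% (d5) to 72.2% (d10) lay above d0 on the later days. Against d14, 47 genes were 2-fold higher and 4 genes 2-fold lower at d1.

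**Figure D1:**
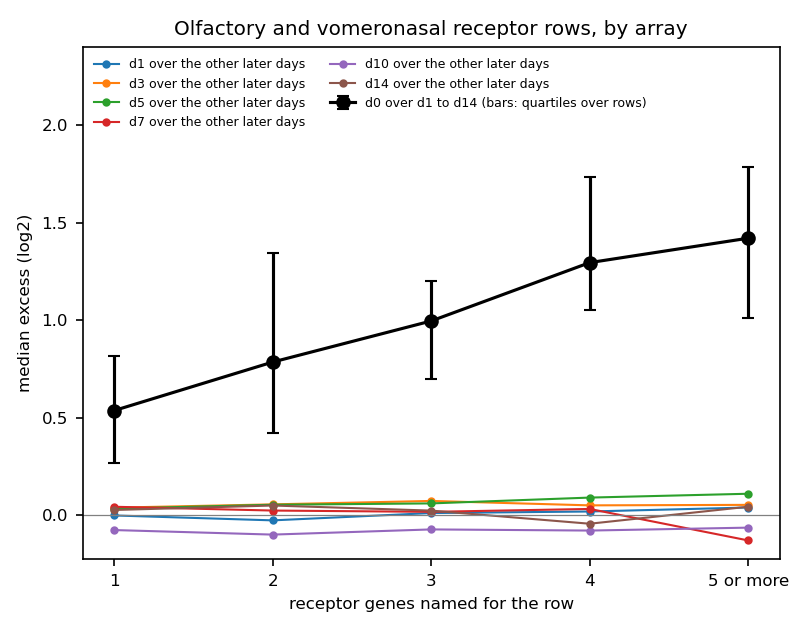
Median log2 excess (vertical axis) over olfactory and vomeronasal receptor rows, by the number of receptor genes a row names (horizontal axis), of d0 over the mean of the 6 later arrays, with quartiles as bars, and of each later array over the other later arrays. The d0 values run from 0.54 for rows with 1 gene to 1.42 for rows with 5 or more, and those of the later arrays lie between -0.13 and 0.11.

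At d3, 50 genes were at least 2-fold higher and 34 at least 2-fold lower than at d0. Csrp3 was still 6.12-fold higher (2.61), and Ankrd2 and Ankrd1 stood at 2.37 and 2.13. Postn, a matricellular protein of connective tissue repair, was 5.45-fold higher (2.45). Myh7, the slow myosin heavy chain, was 3.32-fold higher (1.73), and Cd68 stood at 1.71. Granule genes of neutrophils were among the highest, with Ngp at 2.43 and Lcn2 at 1.85.

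The 12 slow fibre contractile genes had their highest median at d3 (1.11), with 7 of them at least 2-fold higher. Myl6b stood at 1.51, the calcium store protein Casq2 at 1.38 and the troponin Tnnc1 at 1.27. Fibrillar collagen and matrix genes had a median of 0.41 at d3, with 35 of 40 higher, and Timp1 (1.62), Tnc (1.11) and Col8a1 (1.09) followed Postn. Mitosis genes had a median of 0.60 over 12 genes, with Mki67 at 1.31 and Ccna2 at 1.12, and neutrophil markers one of 0.99 over 11 genes. The 4 medians were at percentile 100 of the random lists. Set against d14 they were 0.50, 0.07, 0.38 and 0.87. The filter kept 12 of 39 mitosis genes and 11 of 17 neutrophil markers on the array. With no filter, a setting chosen after the data were seen, the medians at d3 were 0.36 and 0.25. Hmcn1 (-1.26), Arrdc2 (-1.23), Chac1 (-1.23), the short-chain dehydrogenase Dhrs7c (-1.11) and the acetylcholine receptor subunit Chrne (-1.02) were among the lowest. Of the 34 genes that were 2-fold lower, 28 bore symbols of predicted genes, receptors or small RNAs.

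At d5 the same load responsive genes were still high at smaller ratios, with Csrp3 at 2.17, Ankrd2 at 1.91 and Ankrd1 at 1.45. Cxcl13, a B cell attracting chemokine, was 3.82-fold higher (1.93) at d5, against 0.14 at d3 and -0.36 at d7. Postn stood at 2.06, the collagenase inhibitor Timp1 at 1.63, the ketone body enzyme Bdh1 at 1.46 and the slow myosin light chain Myl2 at 1.35. The genes listed as atrophy and FoxO responsive had their lowest median at d5 (-0.17), with the ubiquitin ligase Fbxo32 (atrogin-1) at -0.85, Ddit4 at -0.70, Fbxo31 at -0.40 and Klf15 at -0.38, while Trim63 (MuRF1) stood at -0.17. Glucocorticoid responsive genes had a median of -0.33 at d5, and 12 of 16 were lower, among them Per1 (-0.73), Cebpd (-0.68) and Tsc22d3 (-0.54). Against d14 the medians of these lists were -0.10 and -0.07, the latter at percentile 12.5. In all, 22 genes were 2-fold higher and 38 lower at d5, 30 of the 38 with symbols of predicted genes, receptors or small RNAs.

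At d7, 23 genes were 2-fold higher and 35 lower than at d0, against 1 higher and 2 lower when set against d14. Ankrd2 was 3.36-fold higher (1.75) and Csrp3 stood at 1.74. Actc1, the cardiac actin that muscle also makes during growth, had its highest value at d7, 3.02-fold above d0 (1.60), against 0.96 at d5 and 0.86 at d10. Bdh1 stood at 1.58, Timp1 at 1.53, Myl2 at 1.13 and Postn at 1.09. Macrophage markers had a median of -0.04, at percentile 0.13, with Cd68 at -0.09. Against d14 their median was 0.06, at percentile 99.35, so its sign depends on the reference. Basement membrane genes had a median of 0.30, with Col15a1 at 0.68, Col4a2 at 0.60 and Col4a1 at 0.57, and their median against d14 was 0.03. Of the 35 genes that were lower, 32 bore symbols of predicted genes, receptors or small RNAs. Hmcn1 (-1.22), the immune nuclear protein Sp140 (-1.06) and Arrdc2, with an intensity of 280 against 560 at d0, were lower as well.

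At d10 genes of granulocytes led, and 53 genes were 2-fold higher and 43 lower than at d0. Ngp, a neutrophil granule protein, was 11.0-fold higher (3.46), the calprotectin subunit S100a8 8.96-fold higher (3.16), and the bone sialoprotein gene Ibsp 6.96-fold higher (2.80). Lcn2 stood at 2.83, Ly6a2 at 2.90, Retnlg at 2.39, and the eosinophil granule genes Ear6 and Prg2 at 2.43 and 2.38. At d14 these 8 genes lay between -0.37 (Ear6) and 0.70 (S100a8). Neutrophil markers had a median of 2.27 at d10, with 10 of 11 at least 2-fold higher, against 0.52 at d7 and 0.21 at d14. The list holds 17 genes on the array, and the filter that kept 11 counts the d10 array. With the filter on the other 6 arrays, chosen after the data were seen, the d10 median was 2.31 over 9 genes, and with no filter 1.67 over 17, of which 11 were at least 2-fold higher.

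Mitosis genes were higher at d10 too, with a median of 0.67, Mki67 at 1.48, Ccna2 at 1.39, Plk1 at 1.29 and Ccnb2 at 0.89. The median was 0.71 over the 11 genes that passed the filter on the other 6 arrays, and 0.34 with no filter, when 35 of 39 were higher. In the same array markers of red cell precursors had a median of 0.25 above the mean of d7 and d14, with 6 of 12 past the filter. Markers of osteoclasts, the bone-resorbing cells, had one of 0.31, with 3 of 6 past the filter. Those of bone-forming cells were at -0.04, cartilage at -0.16, B cell precursors at -0.15 and mature neutrophils at -0.03. Genes already seen were left out, namely Ibsp (2.22) of bone, Clec3a (0.96) of cartilage, and Mmp8 (1.82) and Retnlg (2.03) of mature neutrophils. This lowers those 3 medians, so they do not show that such genes were flat. The mature neutrophil markers Cxcr2, Csf3r, Il1r2, Il1b and Cxcr1 also belong to the neutrophil list above. Matrix genes had a median of 0.41 at d10, with Col1a1 at 1.33 and Postn at 1.72, and tendon markers one of 0.42, with Ptx4 at 1.17, Kera at 0.97 and Tnmd at 0.70. Slow fibre genes had a median of 0.74, with Myl2 at 1.54. Against d14 the medians of the neutrophil, mitosis, matrix, tendon and slow fibre lists were 2.18, 0.48, 0.10, 0.09 and 0.43. Of the 43 genes 2-fold lower than d0, 39 bore symbols of predicted genes, receptors or small RNAs.

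At d14, 8 genes were 2-fold higher than at d0 and 39 lower, the smallest number of higher genes among the 6 days. Bdh1 was 2.75-fold higher (1.46), Ankrd2 2.55-fold (1.35), Csrp3 2.15-fold (1.11) and Col1a1 2.12-fold (1.08). Bdh1 lay between 1.45 and 1.64 on all 6 days and between -0.02 and 0.18 against d14, so its difference lay between d0 and the later days. A fault of the d0 array and a low level in suspended muscle cannot be told apart. Hspa1l stood at 1.10, Postn at 1.08, Neto2 and Fthl17f at 1.05. Of the 39 lower genes, 36 bore symbols of predicted genes, receptors or small RNAs. Among named genes Srsy was lowest (-1.92), after values of -2.02 (d7) to -1.50 (d5) on the 5 earlier days. Against d14 it lay between -0.11 and 0.42 on those days, so its difference too lay between d0 and the later days. It was followed at d14 by Sp140 (-1.05), Hmcn1 (-1.03), Arrdc2 (-0.88), the melanocortin receptor Mc5r (-0.86) and the methyltransferase Inmt (-0.84). Matrix genes had a median of 0.27 and basement membrane genes one of 0.32, and stretch responsive genes were at 0.35. Macrophage markers had a median of -0.14, at percentile 0, with 16 of 23 lower and Cd68 at -0.37.

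Contractile and metabolic genes were followed across the days. Myh2, the fast oxidative IIa myosin, was higher by 0.55 at d1 and by 0.96 to 1.08 from d3 on, while the fast myosins Myh1 and Myh4 stayed between -0.12 and 0.18 on all 6 days. The developmental myosins Myh3 and Myh8 were at most 0.61 and 0.09. Fast fibre contractile genes had medians from -0.12 at d1 to -0.01 at d14. Oxidative phosphorylation genes went from a median of -0.08 at d1 to 0.06 at d3, 0.19 at d5, 0.17 at d7, 0.21 at d10 and 0.18 at d14. At d10, Cox4i1 stood at 0.61, Ndufs6 at 0.58, Cox7a1 at 0.48 and Ndufa1 at 0.46. Citric acid cycle genes had medians of -0.08 at d1 and 0.18 at d14, when all 19 were higher, and fatty acid use genes of -0.05 at d1 and 0.29 at d10, with Fabp3 at 0.73, Hadhb at 0.56, Acads at 0.55 and Acadl at 0.52. Set against d14 the medians of these 3 metabolic lists at d1 were -0.31, -0.26 and -0.33, and all 3 lay at or below percentile 0.01.

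Some gene groups differed from d0 by a like amount on all 6 days. Basement membrane genes lay between 0.24 and 0.38, matrix genes between 0.27 and 0.41, PGC-1 and mitochondrial regulators between 0.17 and 0.34, and glucocorticoid responsive genes between -0.33 and -0.15. Against d14 the medians of the regulators lay between -0.04 and 0.01 and those of the glucocorticoid genes between -0.07 and 0.01. Those of basement membrane genes lay between -0.07 and 0.03 on the later days, and d0 was at -0.32. For the groups set against d14 here, the difference thus lay between d0 and the later days. The d0 array also stood apart over receptor genes, and a fault of that array and an effect of suspension cannot be told apart. Receptor rows were higher at d0, as the glucocorticoid genes were, while the basement membrane, matrix and regulator genes were lower at d0. Col1a1 did differ between later days, from 0.12 at d1 through 0.75 at d3 to 1.33 at d10, whereas Col3a1 stood at 0.38 at d1 and between 0.56 and 0.83 afterwards. Of 45 lists that could be ranked, 26, 18, 22, 20, 20 and 21 lay outside the central 95% of random lists at d1, d3, d5, d7, d10 and d14. For lists of genes that vary independently, 2.25 would. In simulated unchanged data with independent noise in each gene, 7.04% of list and day pairs did. Members of a real list can vary together, and all 6 days share the d0 array, so these counts are not a test.

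**Figure D2:**
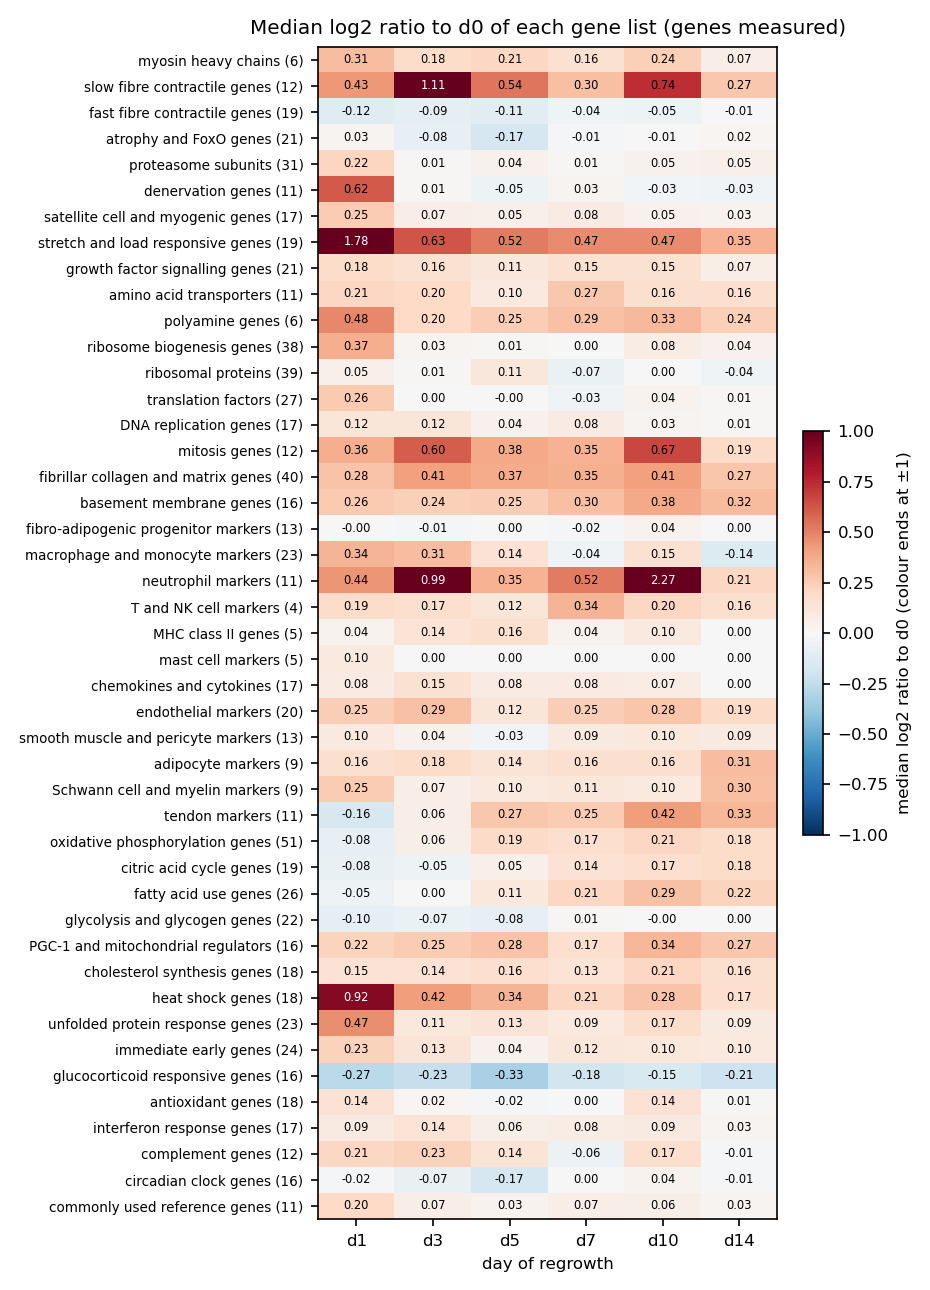
Median log2 ratio to d0 (colour and printed value) of each gene list with at least 4 measured genes (rows, number of genes in brackets) on each day (columns). Stretch and load responsive genes are highest at d1 (1.78), slow fibre genes at d3 (1.11) and neutrophil markers at d10 (2.27).

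Between neighbouring time points 17 genes differed by at least 2-fold from d1 to d3, 5 from d3 to d5, 4 from d5 to d7, 26 from d7 to d10 and 30 from d10 to d14. The d7 and d14 arrays differed at 3 genes, the fewest of the 21 pairs, which bounds how far pooling and chip alone move genes in that pair. From d7 to d10, 23 of the 26 genes were higher, and from d10 to d14, 29 of the 30 were lower, with Ngp, S100a8 and Lcn2 in both. The robust SD of the log2 difference over genes was 0.0896 between d3 and d5 and 0.100 between d10 and d14. Between d0 and the other arrays it was 0.126 (d14) to 0.179 (d1). It was widest between d1 and d7 (0.190), and between d1 and d10 (0.158), d5 (0.150), d14 (0.142) and d3 (0.137) and between d7 and d10 (0.140) it also exceeded that of d0 and d14. The median gene lay 0.05 (d5) to 0.10 (d1) above d0.

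A trend over the days was tested with limma, with the slope of each gene on log2(day + 1). Over the 7 arrays 0 genes rose and 0 fell at a Benjamini-Hochberg adjusted p of 0.05, and the smallest limma adjusted p was 0.0821, for Neto2. At an unadjusted p of 0.05, 1112 genes had a positive and 176 a negative slope, against 833 and 773 without d0 and 1964 and 229 without d1, so the excess of positive slopes depends on d0. Without d0, 19 genes rose and 24 fell from d1 to d14. The limma adjusted p was 0.00355 to 0.0343 for Csrp3, Ankrd2, Hspb1 and Azin1. For the rest it was 0.0469 to 0.0480, just under the bound of 0.05. Those that fell, by the slope per doubling of day + 1, were led by Ankrd1 (-1.15, limma adjusted p 0.0469), Xirp1 (-0.79), Otud1 (-0.71), Csrp3 (-0.71, limma adjusted p 0.00355), the tubulin gene Tubb6 (-0.62), the actin regulator Enah (-0.60), Hsp90aa1 (-0.51) and Ankrd2 (-0.50). Those that rose were led by Odf3l2 (0.43), the tendon gene Tnmd (0.42), Klhl33 (0.36), the mitochondrial isocitrate dehydrogenase Idh2 (0.30) and Ephx2, Ccrl2 and Chad (0.26 each), with Ivd of leucine breakdown at 0.25. No count of rising or falling genes above 0 came from leaving out any other single time point.

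Trends of the list medians were tested over 45 lists with exact permutations of the time points, two-sided. No list passed on Spearman's rho after adjustment over the lists. Median levels of cholesterol synthesis genes came nearest, with a rho of 0.96 (exact p 0.00278, adjusted p 0.125). Their Pearson's r of 0.97 did pass (exact p 0.000595, adjusted p 0.0268), and r was 0.89 without d0 and d1, the time points farthest from the median. This call ended with the list mean (r 0.56), with quantile normalization (r 0.84) and with day on a linear scale (r 0.85). It ended too with each gene centred on its own mean, a setting chosen after the data were seen, where r was 0.71 (adjusted p 0.358) and without d0 0.21. The median ratio of these genes to d0 was 0.13 to 0.21 on the 6 days with no steady order, and Cyp51, Insig1, Dhcr7 and Ggps1 stood between 0.38 and 0.45 at d10. With 1 time point left out, 6 arrays give 720 orders, and a list that passes alone can reach an adjusted p of no less than 0.0625 on r and 0.125 on rho, so a call lost there says nothing. The r of cholesterol synthesis genes was 0.95 to 0.99 in those 7 sets (exact p 0.00139 to 0.00417). Without d0, 6 lists passed on r (exact permutation, adjusted p 0.0417 each) and none on rho (lowest adjusted p 0.107). Stretch and load responsive (r -0.91), heat shock (r -0.94) and polyamine genes (r -0.96) had the negative slopes, and citric acid cycle (r 0.96), fatty acid use (r 0.94) and cholesterol synthesis genes (r 0.95) the positive slopes. With genes centred, 5 lists passed without d0 (adjusted p 0.0312 to 0.0375) and none on rho. Stretch and load responsive (r -0.92), heat shock (r -0.95) and fatty acid use genes (r 0.97) were among them again, and fast fibre contractile (r 0.98) and oxidative phosphorylation genes (r 0.94) were new. Polyamine (r -0.81, adjusted p 0.159), citric acid cycle (r 0.89, adjusted p 0.0703) and cholesterol synthesis genes (r 0.21, adjusted p 0.858) did not pass.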

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

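The data held back from the comparisons carried a signal at d1 against d0. Among 1153 rows with several gene symbols, 2 were at least 2-fold higher and 270 at least 2-fold lower at d1. Among 2620 unannotated rows outside the range of array controls, 6 were higher and 223 lower. Similar numbers were lower on the other days, 245 to 268 of the rows with several symbols, while 10 of those rows were 2-fold higher at d3, 16 at d10, and 0 at d5, d7 and d14. All tests in the next paragraph were chosen after related values had been seen.

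The d0 array, the reference of every ratio, stood apart from the other 6 over receptor genes. Over the 12102 kept genes it hardly did by Pearson's r (mean correlation 0.986, and 0.987 for d1). By Spearman's rho over all 35556 rows it did (mean 0.972, against 0.984 to 0.989 for the others). Over 1194 olfactory and vomeronasal receptor genes, most of which muscle is not known to use, its mean correlation with the other arrays was 0.898, below the lowest other array by 0.0645. Of these, 95 passed the filter. Over the 36 that passed it on a later array, d0 was at 0.857, below the lowest other by 0.0662, where the other 6 spanned 0.0248. This argues against a response of muscle to loading as the whole cause and fits a difference of the sample or its labelling. Genomic DNA in the d0 sample is a candidate explanation, since rows that match many gene copies would then gain most. The median excess of d0 over the mean of the other arrays was 0.54 for receptor rows with 1 symbol, 0.78 with 2, 1.00 with 3, 1.29 with 4 and 1.42 with 5 or more, a difference of 0.884 between the ends, while those of each later array over the other later arrays lay between -0.13 and 0.11. A difference in labelling that acts on such rows by another route stays open, as does a biological change at the end of suspension in the genes of muscle itself, which was not tested.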

How the results depend on the processing

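No paired analysis was possible because each time point is 1 array. The cause of a move below was not tested except where the threshold or the filter sets it. With a 1.5-fold threshold the genes higher at d1, d3, d5, d7, d10 and d14 were 418, 200, 164, 211, 276 and 82 and those lower 123, 102, 97, 104, 100 and 84, and the pairs d1 to d3, d3 to d5, d5 to d7, d7 to d10 and d10 to d14 differed at 131, 34, 44, 203 and 85 genes. With a 3-fold threshold these were 25, 11, 5, 3, 23 and 0 higher, 13, 12, 12, 12, 17 and 15 lower, and 1, 1, 2, 12 and 18 between neighbours. Without the filter on low values the counts of lower genes were 235, 201, 194, 217, 279 and 211, and with the stricter filter 10, 9, 11, 5, 7 and 5, when 17 genes differed from d7 to d10, 19 from d10 to d14, and 1 gene, Neto2, rose with time.

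With d14 as the reference, chosen after the data were seen, 47, 24, 6, 1 and 29 genes were higher at d1, d3, d5, d7 and d10, and 4, 0, 0, 2 and 1 lower. Quantile normalization, equal array medians and the mean of a gene's rows left every 2-fold count within 1.5 times, as all settings tried did the lists outside the central 95%. Leaving out 1 time point gave 0 to 19 rising and 0 to 24 falling genes, the highest without d0, and 0 lists with a trend on rho. On Pearson's r, 0 to 6 lists passed, 6 without d0 and 0 without any other time point, but with 6 arrays at least 2 lists must pass together on r and 3 on rho, so a count of 0 there shows no dependence on a time point. On r, 0 lists passed with the mean in place of the median, with quantile normalization, with day on a linear scale, and with values centred per gene, and 5 passed with values centred and d0 left out, both chosen after the data were seen. Of 209 named genes at the day of their largest ratio, none at 2-fold or more changed sign. Quantile normalization and equal medians moved none of the 209 by more than the robust SD between d10 and d14, and the mean of a gene's rows moved 4 of 208. The mean of the 6 other arrays as the reference moved 167 of 209, and d14 as the reference moved 159 of the 200 genes whose largest ratio was not at d14.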

Other observations

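Several cell type lists had their own courses. Adipocyte markers were highest at d14, with a median of 0.31 over 9 genes, Retn at 0.67, Adipoq at 0.61, Cidec at 0.47 and Plin1 at 0.44, and their medians on the 5 earlier days lay -0.26 to -0.07 from d14. Schwann cell and myelin markers had medians of 0.25 at d1 and 0.30 at d14 and lay between 0.07 and 0.11 on the days between, with Mal at 0.43 and S100b at 0.38 at d14. Endothelial markers lay between 0.12 and 0.29, with Aplnr at 0.90 and Kdr at 0.52 at d3. Against d14 their medians lay between -0.10 (d5) and 0.07 (d3) on the later days, and d0 was at -0.19. Fibro-adipogenic progenitor markers stayed between -0.02 and 0.04, with Lum at 0.76 and Osr1 at -0.28 at d10. Polyamine genes had a median of 0.48 at d1 (0.28 against d14), with Azin1 at 1.25 and Odc1 at 0.88. Clock genes were lowest at d5 (median -0.17), with Per1 at -0.73 and Ciart at -0.55, and Tfrc, the transferrin receptor, stood at 1.26 at d3.

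Among the tests below, those of slow fibre genes and of the orders of time points were chosen after the results were seen. The bounds for the d10 markers were set before, and the condition that an interval lie past a bound was added afterwards, because most markers lie near the floor.

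Granulocyte genes were far higher at d10 than at d7 and d14. Tissue of bone and marrow in the d10 pool may be the source, since Ibsp belongs to bone-forming cells. Over 26 markers not seen before, of bone-forming cells, red cell precursors and granulocyte precursors, the median of d10 over the mean of d7 and d14 was 0.155 (bootstrap interval 0.07 to 0.33), where 0.5 or more was set for this source and under 0.25 against it, and 10 of the 26 passed the filter. Ibsp (2.22), Mpo (1.46) and Elane (1.28) of these sets passed the filter but were left out, because they had been seen. Leaving out such high members lowers the median, so a low value cannot speak against this source. More mature neutrophils alone would leave precursor markers flat. The median of 6 of these was 0.238 (interval -0.02 to 1.00), with 1 of the 6 past the filter. Mpo and Elane, left out of the 6, were not flat, but they had been seen before the markers were chosen. Neither source was excluded. Red cell precursor, osteoclast and granulocyte precursor markers lay at percentile 100 of random lists, with 6 of 12, 3 of 6 and 1 of 6 past the filter. Car1 (0.98) passed it, and Chil3 (1.46) and Rhag (1.09) did not. Of the osteoclast markers, Acp5, Ctsk and Atp6v0d2 were at 0.71, 0.68 and 0.77, but Ocstamp, Dcstamp and Oscar at -0.15, -0.22 and -0.06. Bone-forming cells lay at percentile 57.7, mature neutrophils at 85.6 (median -0.03 over 6 markers, 1 of them past the filter), B cell precursors at 20.1 and cartilage at 2.29. The sets of bone-forming cells, mature neutrophils and cartilage had lost high members that were seen before, such as Mmp8 (1.82) and Retnlg (2.03) of mature neutrophils. Their places are lowered by this. A change in the muscle at d10 was not tested.

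Slow fibre genes were high as a set at d3 and again at d10. All 12 lay above d0 on both days, but only 8 of 12 lay above d7 on both. Against d7, Casq2 and Myl6b were at 0.00 and -0.10 at d10, and Myh7b at -0.07 at d3 and -0.10 at d10. Normalization that depends on intensity would move genes of like intensity alike. Against d7, the median of the slow fibre genes was 0.48 at d3 and 0.33 at d10, while that of sets drawn from the 30 genes nearest to each in mean level was 0.00 and 0.04, and both slow fibre medians lay at percentile 100 of 10000 such sets. The list already lay at percentile 100 against d0 on both days among lists matched in 10 bins of expression. This comparison repeats that with closer matching and another reference, and is not separate support. The smaller excess, 0.290 at d10, argues against such a normalization as the whole cause, and one that acts on single genes was not tested. A share of a slower muscle in these pools could give it, and would raise all slow genes in 1 ratio, but the ratio of the d10 to the d3 increment over the mean of d7 and d14 had a coefficient of variation of 2.41, above the bound of 1 set against this source. Without Myl2 and Myl3, the pair whose removal lowered it most, it was 0.802, a condition added after the value was seen. The d3 increment of Myl3 was only 9.7, which gave a ratio of 24.8. Myh7b had a ratio of 1.76 from increments below 0 on both days. The coefficient thus depends on genes that hardly rose, and the source stays open. Myh7 was 1.52 above d7 at d3 while Myl3, picked after its value was seen, was at -0.03, and a change of fibre type with loading was not tested.

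The trend counts were set against 100 orders of the time points, the real one included. Over 7 arrays the real count was 0, which 100 of 100 orders reach whatever the data, so this decides nothing, and the highest other gave 1. Over the 6 arrays without d0, 1 of 100 orders, the real one, gave as many as the 43 genes, and the highest other gave 0. That set was picked among the 7 that leave out 1 time point, so the highest count over all 7 was also taken under 100 orders. There 1 order, the real one, gave as many as 43, the highest other gave 27, and 8 of the 100 orders gave any gene. A share of 1 in 100 is the smallest that 100 orders can give. It argues against a chance order as the source of the highest count but does not exclude it.

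Equal values were common. Of the 12102 genes, 3226 (26.7%) had 3 or more values among the 7 arrays that were equal to the 1 decimal of the deposited intensities. The d0 array held the shared value in 33.7% of these genes, and the others in 42.2% (d10) to 62.2% (d14).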
